A study of Mus musculus with 12 samples.

How the data were processed

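The labels describe 12 RNA sequencing libraries of mouse testis in 4 groups of 3, labelled control, L.J., busulfan and busulfan plus L.J. Gene expression was deposited by the authors as FPKM, a fragment count scaled to transcript length and to the mapped fragments of a library, 1 value for each gene and library, printed to 2 decimals. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.2 to the mouse build mm10. The quantifier, the annotation, any filter and any scaling between libraries are not given in the sources used here. Read counts were not used here, so the depth of each library is unknown and no counting error can be given. Raw reads were not analysed here.

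The table holds 21004 genes. Its 26 symbols with the form of a date were replaced by gene identifier from the RefSeq annotation of GRCm38, where 20841 identifiers, 99.2%, were found. Positions are those of that annotation. Genes were kept when they had at least 1 FPKM in at least 3 libraries, which left 14675 genes and removed 6329. Values were taken as deposited and transformed as log2(FPKM + 1), so changes of genes near 1 FPKM are smaller than their ratio of FPKM. Means and SDs are of FPKM, and changes are of the log2 values.

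All 4 groups entered 1 linear model per gene, fitted with limma 3.58.1 in R 4.3.3 with trend and without the robust option (8 residual degrees of freedom, 3.4 prior degrees of freedom). Contrasts compared busulfan with control, busulfan plus L.J. with busulfan, L.J. with control and busulfan plus L.J. with control, and tested the interaction of both treatments. The comparison of busulfan plus L.J. with L.J. was added after the data were seen. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, with a threshold of 0.05. A restored gene was defined as past the threshold in busulfan against control and in busulfan plus L.J. against busulfan in opposite directions. The fit was tested on simulated data of the same layout, with the same spread of a gene in all groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

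The design, the gene lists, the named-gene rule and the alternatives were set before the data were examined, apart from those called added. The 29 lists were spermatogonia, meiotic spermatocytes, round spermatids, elongating spermatids, Sertoli cells, Leydig cells and steroidogenesis, peritubular myoid cells, extracellular matrix, macrophages, lymphocytes, endothelial cells, erythroid cells, epididymis, adipocytes, blood-testis barrier and junctions, antioxidant defence, p53 response, apoptosis, inflammation, interferon response, antigen presentation, cholesterol synthesis, retinoic acid metabolism, piRNA pathway and retrotransposon silencing, glycolysis and energy of sperm, circadian clock, immediate early genes, cell cycle and mitochondrial mRNA. The last has 13 members, of which 0 are in the table, so 28 lists were tested. Trbc1, Trbc2 and Mx1 of other lists were not found either. Lists were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the 28 lists. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. Members were also adjusted over the list alone.

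Genes were named by a rule with 4 parts. The first took the 8 largest increases and 8 largest decreases past the threshold with groups that did not overlap and at least 5 FPKM in the higher group, passing over predicted, non-coding and histone genes. The second took the first 3 members of each list, and the third up to 2 more members with the largest change where members passed. The last took the 3 higher and 3 lower genes with the smallest p where no gene passed. Members of the second part were left out of the text to keep it short, and genes outside the rule are said to be chosen after their values were seen. Single results of some genes that the rule names are not given.

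Alternatives were a replicate block, a fit of the 2 groups compared, pseudocounts of 0.1 and 5, no filter, a minimum of 5 FPKM, quantile normalization, scaling to the median or to Sertoli markers, limma robust without trend, array weights, an absolute log2 change of at least 1, and leaving out each library in turn. Where a library is left out, its group keeps 2. A list of 20 other fat genes was also written after the data were seen, to replace a count of the adipocyte list that restated what it was to test. Added after the data were seen were a covariate for germ cell content, a fit without L.J. replicates 2 and 3, and array weights estimated gene by gene, because the default estimate did not converge. Each comparison was also made on other splits of the same libraries, all 10 where 2 groups were compared and 100 drawn at random for the interaction and the restored genes.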

Results

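Messenger RNA was measured by sequencing in the testis of 8-week-old ICR mice, an outbred strain, with 12 libraries in 4 labelled groups of 3. The groups are labelled control, busulfan, L.J. at 10 mg/kg, and busulfan plus L.J. at 10 mg/kg. Busulfan is an alkylating drug that is toxic to dividing germ cells, and L.J. is an agent that the labels do not explain further. The series text also speaks of FMT without explaining it, so what the groups labelled L.J. received is uncertain. The dose of busulfan and the days between treatment and sampling are not given in the sources used here. The labels do not say whether the 3 libraries of a group are separate animals, so every p-value measures the spread between samples. The values are FPKM, 1 per gene and library, as deposited. They sum to between 417242 and 535515 per library, and between 18674 and 19151 genes lie above 0. The files hold no read counts, so the depth of each library is unknown. Directions below are those of the libraries as labelled, and groups are called by their labels throughout.

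The libraries labelled busulfan and busulfan plus L.J. looked alike, while those labelled control and L.J. varied widely in their mix of germ cell and somatic transcripts. The mean log2(FPKM + 1) of the list of elongating spermatids, the germ cells that condense their chromatin and build the tail, was between 9.12 and 9.36 in the 6 libraries labelled busulfan or busulfan plus L.J. It was 6.52, 7.71 and 6.06 in control replicates 1 to 3 and 7.21, 8.50 and 6.55 in L.J. replicates 1 to 3. The mean of the list of Sertoli cells, the supporting cells of the seminiferous tubule, ran the other way, from 3.86 to 4.12 in those 6 libraries and from 4.57 to 6.66 in the other 6. L.J. replicates 2 and 3 lay at the ends of this range, with 4.57 in replicate 2 and 6.66 in replicate 3. The first principal component held 79% of the variance. Its scores were between -55.0 and -38.2 in the 6 libraries labelled busulfan or busulfan plus L.J., and 31.1, -12.4 and 98.6 in L.J. replicates 1 to 3. Pearson correlations across genes between libraries of a group were 0.867 to 0.969 for L.J. and 0.955 to 0.978 for control. They were 0.981 to 0.989 for busulfan and 0.987 to 0.989 for busulfan plus L.J. The median SD of log2 values was 0.423 for L.J., 0.192 for control, 0.163 for busulfan and 0.12 for busulfan plus L.J. The fit of all 4 groups takes these spreads as equal. Its p-values can therefore be too small where the L.J. group is compared and too large for busulfan plus L.J. against busulfan. The 10 most abundant genes took 4.4% to 5.2% of the FPKM sum in the control and L.J. libraries, except 8% in L.J. replicate 2, and 9.1% to 13.6% in the other 6.

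**Figure D1:**
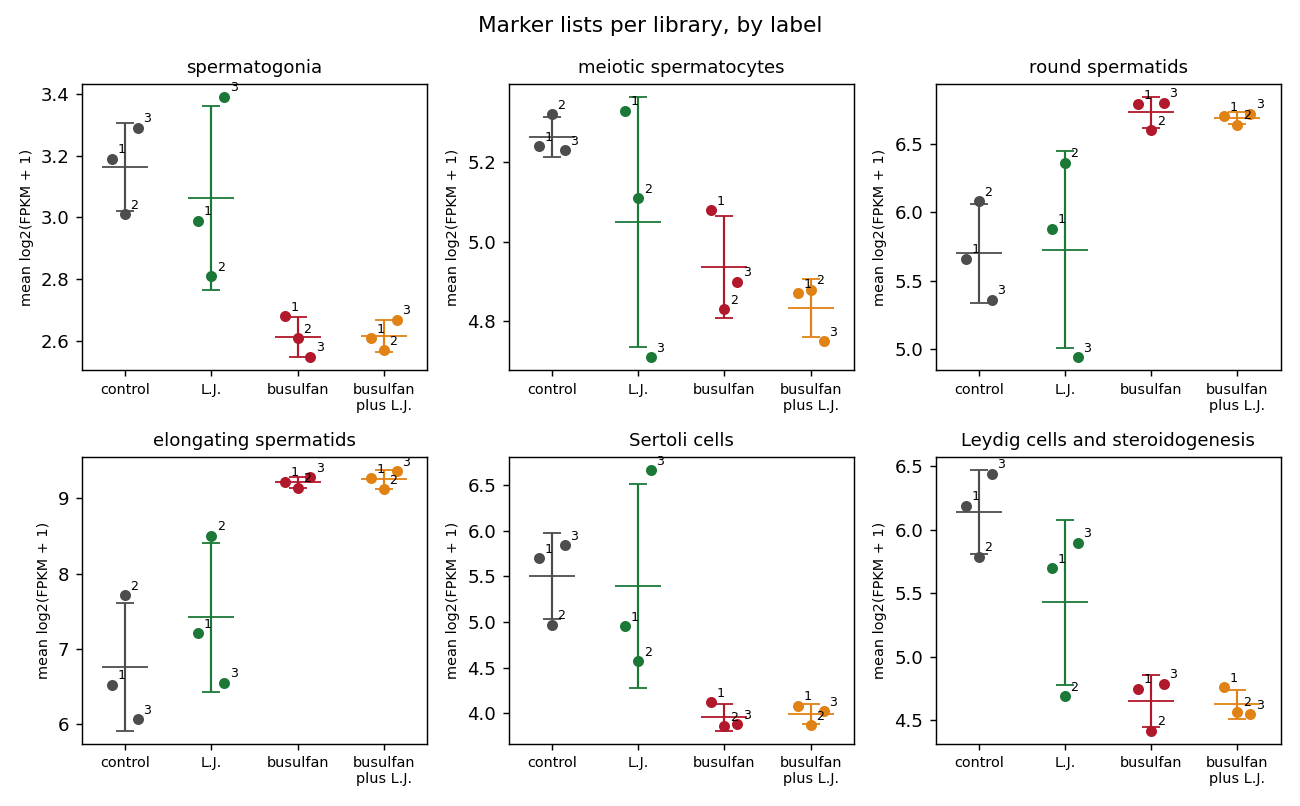
Mean log2(FPKM + 1) of 6 marker lists in each of the 12 libraries, grouped by label, with the replicate number beside each point and the group mean ± SD as lines. The Sertoli list lies between 3.86 and 4.12 in the 6 libraries labelled busulfan or busulfan plus L.J. and between 4.57 and 6.66 in the others.

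The comparison of busulfan with control asks what the drug does to the testis. In the libraries labelled busulfan, transcripts of late spermatids were much higher, and as deposited those of Sertoli cells, Leydig cells, macrophages and extracellular matrix were lower. The macrophage and matrix lists turned to 0.03 and 0.20 when scaled to Sertoli markers. Genes that pack DNA in spermatids rose, with Prm2, Tnp2 and Tnp1 among the 8 largest increases named below. Prm1, a protamine (gene 19118, chromosome 16, 10796332 to 10796823, GRCm38), was 4571 ± 1181 FPKM (SD, n = 3) in the busulfan libraries and 655 ± 634 in the control libraries. Its log2 fold change was 3.19 ± 0.67 (SE), with an adjusted p of 0.00467 by limma. Tnp2, a transition protein (gene 21959, chromosome 16, 10787935 to 10788655), was 9310 ± 1618 FPKM against 966 ± 840, a log2 fold change of 3.61 ± 0.65. Insl3, a peptide hormone of Leydig cells (gene 16336, chromosome 8, 71689252 to 71690577), was 876 ± 135 FPKM against 3515 ± 971, a log2 fold change of -1.98 ± 0.46. Clu, a secreted chaperone of Sertoli cells (gene 12759, chromosome 14, 65968483 to 65981548), was 361 ± 19.9 FPKM against 1216 ± 393, a log2 fold change of -1.69 ± 0.50. Its adjusted p of 0.0138 became 0.0528 without control replicate 3.

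In all, 9350 of 14675 genes passed limma's threshold in this comparison, 1814 higher and 7536 lower in the libraries labelled busulfan. Both groups did not overlap for 11267 genes, or 76.8%, where chance gives 10%. A fit of these 2 groups alone called 10396 genes. The direction of most calls rests on the scaling, since the median log2 change of all genes was -0.51 as deposited, 0.05 after scaling each library to its median and 0.96 after scaling it to Sertoli markers. Of the calls, 19.4% were higher as deposited, 47% after quantile normalization, 68.6% of 4519 after median scaling and 100% of 2932 after scaling to Sertoli markers. Without control replicate 3 the count was 5842. Without L.J. replicates 2 and 3, which stand apart, it was 10942. Camera called 10 of 28 lists, 4 higher and 6 lower, none with an estimated correlation, and fry called 18. Relative to the median of all genes, the list medians were 3.19 for elongating spermatids, 1.71 for round spermatids, -0.03 for meiotic spermatocytes, -0.18 for spermatogonia, -1.02 for Sertoli cells and -1.04 for Leydig cells. Where a single count is given for a list, that adjusted over the list alone was the same.

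The lists of spermatid genes were higher in the libraries labelled busulfan under each of the 3 scalings. Of 26 genes in the list of elongating spermatids, 24 rose and none fell, with a median log2 change of 2.68 as deposited and 4.15 scaled to Sertoli markers. Of 22 genes of round spermatids, 14 rose and none fell, with a median of 1.2. By camera the adjusted p was 1.79e-20 for the elongating and 3.32e-10 for the round spermatid list, and for both it was 0.853 with an estimated correlation. Odf1, a protein of the sperm tail, rose by 2.77 log2, and Gapdhs, the glycolysis enzyme of sperm, by 2.82. Acrv1 and Spaca1, both of the acrosome, rose by 1.49 and 1.24, while Acrbp of the same list had a log2 change of 0.31 (adjusted p = 0.342 by limma). The largest increases among genes whose groups did not overlap were those of Zc2hc1b (3.72), Prm2 (3.62), Tnp2, Tnp1 (3.47), Arl9 (3.47), Tppp2 (3.43), Trp53tg5 (3.38) and Spata3 (3.36). The list of glycolysis and energy genes of sperm had 6 of 17 genes higher and none lower (camera adjusted p = 0.00277, adjusted p = 0.858 with an estimated correlation). Its median was 0.14, and -0.04 after quantile normalization. It was 0.22, 0.08 and 0.07 without control replicate 2, control replicate 3 and busulfan replicate 1.

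Lists of earlier germ cells had medians below 0 as deposited and after quantile normalization, and above 0 after scaling to Sertoli markers. Of 20 spermatogonial genes, 12 were lower and 1 higher, with a median of -0.69 as deposited, -0.13 after median scaling, -0.27 after quantile normalization and 0.78 scaled to Sertoli markers. The higher one was Lhx1 (0.99), with means of 0.29 FPKM in control and 1.55 in busulfan. Of 32 meiotic genes, 17 were lower and 2 higher, and 16 and 2 when adjusted over the list alone. Their median of -0.54 was -0.22 after quantile normalization, 0.02 after median scaling and 0.93 after scaling to Sertoli markers. The higher ones were Pgk2 (1.51), a glycolysis enzyme of late germ cells, and Syce2 (1.29), of the synaptonemal complex. Camera called neither list, with adjusted p of 0.442 and 0.792. Among the first genes of these lists, Kit, a receptor of differentiating spermatogonia, had a log2 change of -1.35 and Dmc1, a recombinase of meiosis, of -0.84. Gfra1, a receptor of spermatogonial stem cells, had 0.32 (adjusted p = 0.089 by limma; 0.044 without L.J. replicate 2 and 0.0327 without L.J. replicate 3). Zbtb16, a factor of undifferentiated spermatogonia, had -0.88, and its adjusted p of 0.0195 became 0.0725, 0.0601, 0.0601 and 0.0520 without control replicates 1 and 3 and busulfan replicates 1 and 3. Sycp3, of the synaptonemal complex, had -0.51, and its adjusted p of 0.0294 became 0.115, 0.0609, 0.0707 and 0.0856 without the same libraries. Sycp1, of the same complex, had -0.47 with an adjusted p of 0.0491, which passed 0.05 without any 1 of 8 libraries. Those were control replicates 1 (0.160), 2 (0.0925) and 3 (0.0601), busulfan replicates 1 (0.132) and 3 (0.143), and busulfan plus L.J. replicates 1 (0.0658), 2 (0.0590) and 3 (0.0514). The list of piRNA factors, which silence transposons, had 8 of 18 genes lower and Dnmt3l (0.81) higher, with a median of -0.48 that was -0.29 after quantile normalization, 0.08 after median scaling and 0.99 scaled to Sertoli markers (camera adjusted p = 0.795). The cell cycle list had 16 of 23 genes lower, with a median of -0.53 that was -0.18, 0.03 and 0.94 in the same order (camera adjusted p = 0.101). Its first gene Mki67 had -0.59, which turned to 0.87 scaled to Sertoli markers.

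All 23 Sertoli genes and all 18 Leydig genes tested were lower in the libraries labelled busulfan as deposited. The medians were -1.53 and -1.55, with camera adjusted p of 0.0145 and 0.00368, and an adjusted p of 0.858 for both with an estimated correlation. Star, which brings cholesterol into the mitochondrion, and Cyp17a1, an enzyme of androgen synthesis, had log2 changes of -1.88 and -1.73. Sox9 and Wt1, factors of Sertoli cell identity, had -1.19 and -1.47. The adjusted p of Wt1, 0.0151, became 0.0514 without control replicate 1 and 0.0551 without control replicate 3. That of Sox9, 0.0485, became 0.134, 0.123, 0.0699, 0.0976 and 0.128 without control replicates 1 and 3 and busulfan replicates 1, 2 and 3, and 0.0611, 0.0594 and 0.0629 without busulfan plus L.J. replicates 1, 2 and 3. Of 10 genes of peritubular myoid cells, the contractile cells around the tubule, 9 fell, among them Acta2 (-1.73), and Actg2 rose (2.04). Their median was -1.53 (camera adjusted p = 0.230). After scaling to Sertoli markers the medians were -0.06, -0.08 and -0.07 for the Sertoli, Leydig and myoid lists, and the first of these is set by that scaling.

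Of the other somatic and tissue lists, camera called extracellular matrix and macrophages lower as deposited in the libraries labelled busulfan, with medians above 0 when scaled to Sertoli markers, and lymphocytes higher. Of 22 genes of extracellular matrix, 20 were lower, with a median of -1.26 (0.20 scaled; camera adjusted p = 0.0188, adjusted p = 0.858 with an estimated correlation). Of 17 macrophage genes, 15 were lower, among them Csf1r (-1.59) and the complement gene C1qa (-1.87). Their median was -1.43 (0.03 scaled; camera adjusted p = 0.0302, adjusted p = 0.858 with an estimated correlation). The macrophage call was lost without busulfan replicate 1 (0.0578) or L.J. replicate 3 (0.0559). The 1 macrophage gene that rose was Aif1 (2.39), a calcium-binding protein, from 73.8 ± 34.9 to 368 ± 52.0 FPKM. Of 16 lymphocyte genes found in the table, only 6 passed the filter on low values. Of these 6, Cd3d (0.70), Cd2 (1.06) and Cd8b1 (0.49), all below 5 FPKM, were higher and none lower. Cd8b1 reached 1 FPKM only in libraries labelled busulfan or busulfan plus L.J., so the filter itself favours a higher value there for such a gene. The direction of the lymphocyte list is thus no measure of the number of lymphocytes. The median of that list was 0.55 and stayed above 0 under each scaling (camera adjusted p = 0.0188, adjusted p = 0.853 with an estimated correlation; 0.0572 without busulfan replicate 2, with a median of 0.27). For Cd2 limma's adjusted p of 0.0144 became 0.0558 without control replicate 1 and 0.0557 without busulfan replicate 2. For Cd8b1 the adjusted p of 0.0196 became 0.0785, 0.0633 and 0.0765 without control replicate 1, busulfan replicate 2 and busulfan replicate 3. Of 13 endothelial genes, 6 were lower and Flt1 (0.37) was higher, with 5 lower when adjusted over the list alone (median -0.62, 0.85 scaled; camera adjusted p = 0.792). Limma's adjusted p of Flt1, 0.0370, became 0.127 and 0.0944 without control replicates 1 and 3, and 0.112 and 0.0758 without busulfan replicates 2 and 3. Of 8 erythroid genes, Hbb-b1 (-1.85) passed, and no gene passed when adjusted over the list alone (median -0.83, -0.48 without control replicate 3, 0.64 scaled; camera adjusted p = 0.819). The adjusted p of Hbb-b1, 0.0182, became 0.0515 and 0.0568 without control replicates 2 and 3, and 0.0543 and 0.0628 without busulfan replicates 1 and 3. Haemoglobin genes are near-identical copies, so their single values are uncertain.

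Among lists of stress, defence and metabolism, camera called those of apoptosis and cholesterol synthesis lower in the libraries labelled busulfan as deposited, and both medians turned positive under the same scaling. Of 25 antioxidant genes, 20 were lower, among them Cat (-1.48), the catalase, and Prdx4 (0.92) and Srxn1 (1.32) were higher (median -1.22, 0.25 scaled to Sertoli markers; camera adjusted p = 0.121). Of 23 genes induced by p53 after DNA damage, 17 were lower, 19 when adjusted over the list alone, and Polk (0.55), a DNA polymerase, was higher (median -0.86, 0.61 scaled; camera adjusted p = 0.121). Cdkn1a, a brake on the cell cycle, had -0.79, Mdm2 -0.19 (adjusted p = 0.221 by limma) and Bax -1.40, and Cdkn1a, Mdm2 and Bax turned to 0.67, 1.27 and 0.06 when scaled to Sertoli markers. The adjusted p of Cdkn1a, 0.0396, became 0.0997 and 0.150 without control replicates 1 and 3, and 0.0957, 0.0550 and 0.102 without busulfan replicates 1, 2 and 3. It became 0.0525, 0.0534 and 0.0528 without busulfan plus L.J. replicates 1, 2 and 3. Of 22 apoptosis genes, 17 were lower, 20 when adjusted over the list alone. The median of that list was -0.91 (0.55 scaled; camera adjusted p = 0.0302, adjusted p = 0.858 with an estimated correlation; 0.0578 without busulfan replicate 1). Of 19 genes of cholesterol synthesis, 16 were lower, among them Hmgcs1 (-1.53) and Msmo1 (-2.07). The median of that list was -1.28 (0.18 scaled; camera adjusted p = 0.0145, adjusted p = 0.858 with an estimated correlation; 0.0587 without L.J. replicate 3).

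The remaining lists were not called by camera in this comparison. Of 20 junction genes of the seminiferous epithelium, 13 were lower, among them Gja1 (-1.64), of gap junctions (median -1.09, 0.38 scaled to Sertoli markers; camera adjusted p = 0.261). Of 15 genes of retinoic acid metabolism, 10 were lower, among them Aldh1a1 (-1.65; median -0.91, 0.56 scaled; adjusted p = 0.230). Of 12 inflammation genes, 8 were lower, 10 when adjusted over the list alone, and the chemokine Ccl5 (0.78) was higher (median -0.90, 0.57 scaled; adjusted p = 0.183). For Ccl5 limma's adjusted p of 0.0260 became 0.102 without control replicate 1, and 0.0573, 0.0678 and 0.0567 without busulfan replicates 1, 2 and 3. Of 12 interferon genes, 8 were lower (median -0.79, 0.67 scaled; adjusted p = 0.186). Of 14 antigen presentation genes, the class I members H2-K1 (-1.41), H2-D1 (-1.79), B2m (-1.76), Tapbp (-1) and Psmb8 (-0.71) were lower (median -0.63, 0.83 scaled; adjusted p = 0.681). H2-K1, Tapbp and Psmb8 turned to 0.05, 0.46 and 0.76 when scaled, and the H2 genes are near-identical copies. Limma's adjusted p of Tapbp became 0.0540 and that of Psmb8 0.123 without control replicate 3, 0.0501 and 0.0639 without busulfan replicate 2, and that of Psmb8 0.0905 without busulfan replicate 3. Of 16 clock genes, 10 were lower, 11 when adjusted over the list alone, among them Dbp (-1.46), and Per1 (0.85) was higher (median -0.77, 0.70 scaled; adjusted p = 0.183). Of 13 immediate early genes, 6 were lower and Fosb (0.47), Klf4 (0.78) and Nr4a1 (1.34) higher. Their median was -0.95 (0.52 scaled) and their camera direction was up (adjusted p = 0.442). The adjusted p of Fosb by limma became 0.0840 without control replicate 1 and 0.0675 without busulfan replicate 2, and that of Klf4 0.0852, 0.0526 and 0.0516 without control replicate 3 and busulfan replicates 2 and 3. Of 8 adipocyte genes, 6 were lower (median -1.12, -0.64 without control replicate 3, 0.34 scaled; adjusted p = 0.681). Genes in this and the preceding 2 paragraphs outside the first members and the largest changes of a list were named after their values were seen.

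The 4 largest decreases rested in part on control replicate 3. Crisp1 (-4.52), Cd52 (-3.46), Akr1b7 (-3.46) and Spink8 (-3.24), genes known from the epididymis or vas deferens, were 503, 215, 332 and 116 FPKM in that library. They were at most 15.1, 8.36, 12.4 and 4.16 FPKM in the other 2 control libraries. Without control replicate 3, Crisp1 had a log2 change of -2.37 (adjusted p = 0.114 by limma) and Cd52 of -1.74 (adjusted p = 0.0817), while Akr1b7 and Spink8 each had -1.56 and stayed past the threshold. Limma's adjusted p of Akr1b7 became 0.0554, 0.0751 and 0.0577 without busulfan replicates 1, 2 and 3, that of Cd52 0.0624, 0.0719 and 0.0567, that of Crisp1 0.0652, 0.0699 and 0.0709, and that of Spink8 0.0537, 0.0656 and 0.0577. Of 5 genes on the epididymis list, Cst8 (2.33) and Defb21 (1.89) were higher and Crisp1 and Wfdc10 (-1.88) lower (median -0.08, 0.48 after median scaling, 0.47 after quantile normalization and 1.39 scaled to Sertoli markers). Without control replicate 3 or busulfan replicate 2 that median turned to 0.04 and 0.03, and without control replicate 1 it was -0.25. Its camera direction was up (adjusted p = 0.152). Limma's adjusted p of Wfdc10 became 0.0599 without control replicate 3 and 0.0584 without busulfan replicate 2. The other genes with the largest decreases were Vgll2 (-2.91), Ibsp (-2.80), Car3 (-2.74) and Igfbp3 (-2.66).

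**Figure D2:**
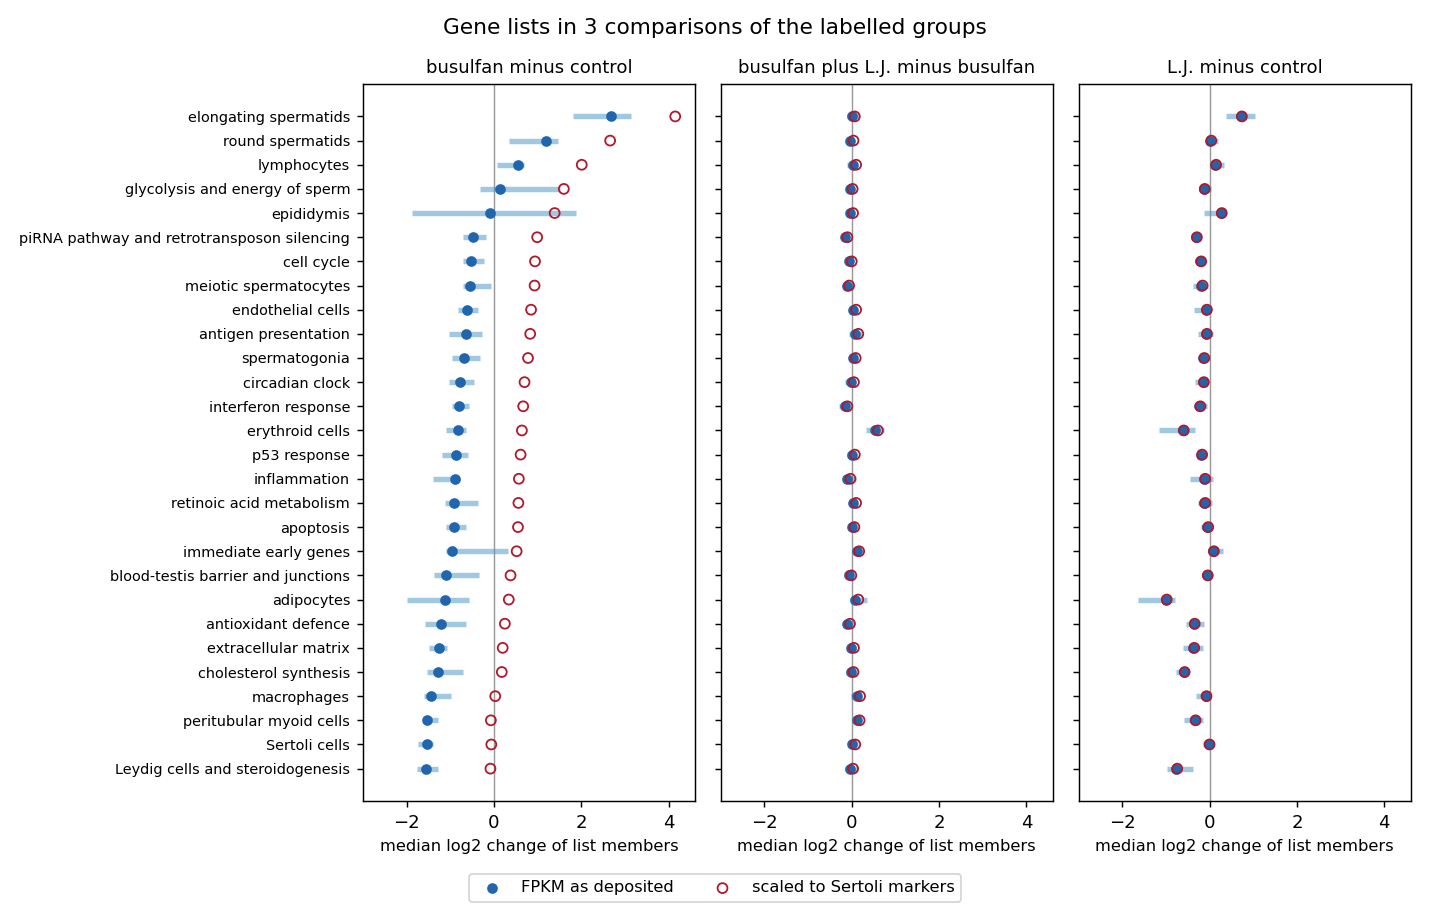
Median log2 change of each gene list in 3 comparisons, with bars from the lower to the upper quartile of its genes for FPKM as deposited (filled points) and open points after scaling to Sertoli markers. In busulfan minus control the elongating spermatid list lies at 2.68 as deposited and 4.15 scaled, and the macrophage list moves from -1.43 to 0.03.

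The comparison of busulfan plus L.J. with busulfan is the one the series title asks about, whether L.J. counters the effect of the drug. The 2 groups of libraries had nearly the same transcript levels. Prm1 was 4079 ± 475 FPKM (SD, n = 3) with L.J. and 4571 ± 1181 without, a log2 change of -0.14 with a 95% interval from -1.60 to 1.33. Clu had a log2 change of 0.12 (-0.96 to 1.21), Cyp17a1 of -0.06 (-0.92 to 0.80), Insl3 of 0.24 (-0.78 to 1.25) and Sycp3 of 0.08 (-0.32 to 0.48). The medians of the lists were 0.00 for elongating spermatids, 0.01 for Sertoli cells, -0.03 for Leydig cells and 0.02 for spermatogonia.

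No gene passed limma's threshold in busulfan plus L.J. against busulfan (lowest adjusted p = 1), and 109 genes, 0.74%, lay at an unadjusted p under 0.05. A fit of these 2 groups alone called 1 gene and held 465 at an unadjusted p under 0.05. The groups did not overlap for 1259 genes, 8.6%, where chance gives 10%. The 95% interval of the change lay within 1 log2 of 0 for 13150 genes, 89.6%, and for 14239, 97%, in the fit of these 2 groups. In simulated data of the same layout limma recovered 45% of genes changed by 1 log2 and 90% of those changed by 2. The simulation gave all groups the same spread per gene, so it does not give the recovery at the smaller spread of these 2 groups. It also changed only genes with a mean log2(FPKM + 1) above 2, so it does not give the recovery of lower genes. The genes with the smallest p were Gm20823 (1.47), Vgll2 (3.01), Gm4297 (0.86), Zfp868 (-1.03), Gm9780 (-1.56) and Rex1bd (-1.05), all with an adjusted p of 1. Gm20823, a gene of chromosome Y with like copies, at most 2.18 FPKM in any library, was the gene called in the fit of the 2 groups (adjusted p = 0.0357). Vgll2, a cofactor of transcription, was 21.8 ± 5.98 FPKM with L.J. and 3.92 ± 6.18 without. Without busulfan replicate 3 its log2 change was 4.07 (adjusted p = 0.00528 by limma), and it was the only gene called.

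Of 28 lists tested in this comparison, camera called erythroid cells and macrophages, both higher with L.J. None of the members of any list passed over all genes or adjusted over the list alone. The erythroid list of haemoglobins and red cell markers had a median of 0.54 (adjusted p = 0.000409, adjusted p = 0.977 with an estimated correlation). Hba-a1, a haemoglobin, was 299 FPKM in busulfan plus L.J. replicate 3, and 83.2 and 47.5 in replicates 1 and 2. Without that library the erythroid median was 0.11 (adjusted p = 0.654), and without busulfan replicate 3 it was 0.36. The macrophage list had a median of 0.12 (adjusted p = 0.0247, adjusted p = 0.977 with an estimated correlation). Its adjusted p was 0.281 without busulfan plus L.J. replicate 3, 0.0612 without busulfan replicate 1 and 0.0783 without busulfan replicate 2, and its median was 0.19 without busulfan plus L.J. replicate 2. By fry no list passed (adjusted p = 0.982 for each). With each of the 12 libraries left out in turn, camera also called lists that it did not call with all libraries. Those were the piRNA and immediate early lists 4 times each, interferon 3 times and antigen presentation 2 times. Lymphocytes and meiotic spermatocytes were called 1 time each.

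No gene met the definition of a restored gene, which was a pass in busulfan against control and a pass in the opposite direction in busulfan plus L.J. against busulfan. At an unadjusted p under 0.05 in both, 45 genes were found, and 23 of them, 51.1%, went in opposite directions. Both comparisons share the busulfan libraries, which favours opposite directions by chance for genes that busulfan does not change. In 50 simulations of groups unchanged in both comparisons, a mean of 182.2 such genes was found, and 98.6% went in opposite directions. Here 9350 genes passed in busulfan against control, so these simulations are no reference for the 51.1%. Without busulfan replicate 3 the count of restored genes was 1, and the only gene called in busulfan plus L.J. against busulfan without that library was Vgll2.

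The comparison of L.J. with control asks what L.J. does without the drug. No gene passed limma's threshold (lowest adjusted p = 0.843), and 715 genes, 4.87%, lay at an unadjusted p under 0.05. Tested as lists by camera, Leydig cells had a median of -0.76 and elongating spermatids of 0.72, each with an adjusted p of 0.533 with an estimated correlation. Without L.J. replicate 2 these medians were -0.27 and 0.13. The list of round spermatids had a median of 0.02 (camera adjusted p = 0.164) that depended on single libraries. It was -0.25 (adjusted p = 0.00158), 0.44 (1.27e-08) and 0.19 (0.000419) without L.J. replicate 2, L.J. replicate 3 and control replicate 2, and turned to -0.11 and -0.07 without control replicate 3 and L.J. replicate 1. Cyp17a1 was 300 ± 194 FPKM with L.J. (SD, n = 3) and 778 ± 135 in control, a log2 change of -1.58 ± 0.39 (SE), and of -1.06 without L.J. replicate 2. Prm1 was 1289 ± 1150 against 655 ± 634 FPKM, a log2 change of 1.03 with a 95% interval from -0.43 to 2.50. That of Prm1 was 0.34 without L.J. replicate 2, 0.57 without control replicate 3 and 1.79 without control replicate 2. A fit of these 2 groups alone called 0 genes, with 314 at an unadjusted p under 0.05. The groups did not overlap for 1331 genes, 9.1%, where chance gives 10%. The 95% interval lay within 1 log2 of 0 for 12085 genes, 82.4%, and for 9732, 66.3%, in the fit of these 2 groups alone. In simulated data 43% of genes changed by 1 log2 and 89% of those changed by 2 were recovered. That simulation gave all groups the same spread per gene, so these shares may not hold at the wider spread of the L.J. libraries. They do not cover the low genes that the simulation left unchanged. With germ cell content as a covariate, a choice made after the data were seen, 0 genes passed. The genes with the smallest p were Gm46320 (0.75), Mpig6b (0.64), Gm48909 (0.66), Thrsp (-2.15), Fads3 (-1.11) and Lrrc17 (-1.34), each with an adjusted p of 0.843. Thrsp, a regulator of fat synthesis, was 0.990 ± 0.586 FPKM with L.J. and 7.79 ± 2.36 in control.

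Camera called 11 of the 28 lists in L.J. against control, and with an estimated correlation or by fry it called none. The list of elongating spermatids was higher (median 0.72, adjusted p = 1.90e-11, adjusted p = 0.533 with an estimated correlation), and without L.J. replicate 2 its median was 0.13 (adjusted p = 0.178). The median of elongating spermatids was 1.23, 0.34 and 1.12 without control replicates 2 and 3 and L.J. replicate 3. The Leydig list was lower (median -0.76, adjusted p = 4.56e-07, adjusted p = 0.533 with an estimated correlation), and without L.J. replicate 2 its median was -0.27. When adjusted over the list alone, 5 of its 18 genes passed. They were Cyp11a1 (-1.75), Cyp17a1 (-1.58), Lhcgr (-1.42), Star (-1.04) and Fdx1 (-0.92), enzymes and carriers of androgen synthesis and, in Lhcgr, the receptor that controls it. The list of cholesterol synthesis was lower (median -0.59, adjusted p = 1.93e-10, adjusted p = 0.533 with an estimated correlation), with Fdps (-0.90) passing when adjusted over the list alone. Its median was below 0 without any 1 library, between -0.81 and -0.36, the latter without L.J. replicate 2. The adipocyte list was lower (median -1, adjusted p = 2.69e-05, adjusted p = 0.533 with an estimated correlation), with 6 of 8 genes passing when adjusted over the list alone, and without L.J. replicate 3 its adjusted p was 0.263 while its median stayed at -0.95. Its median was -0.61 without control replicate 3. These 4 medians kept their sign under each scaling.

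The other lists called in this comparison had small medians and depended on single libraries. The list of extracellular matrix had a median of -0.38 (adjusted p = 0.00222, adjusted p = 0.962 with an estimated correlation), with Col3a1 (-1.25) and Lum (-0.67) passing when adjusted over the list alone. Its adjusted p was 0.292, 0.132 and 0.0608 without L.J. replicate 2, control replicate 3 and L.J. replicate 1, and its median was -0.59 and -0.17 without control replicates 2 and 3. The antioxidant list had -0.36 (adjusted p = 0.0232, adjusted p = 0.962 with an estimated correlation), with 0.628, 0.268 and 0.194 without the same libraries. The piRNA list had -0.31 (adjusted p = 0.000584, adjusted p = 0.780 with an estimated correlation; 0.654 without L.J. replicate 3 and 0.102 without control replicate 2). The meiotic list had -0.19 (adjusted p = 0.0368, adjusted p = 0.962 with an estimated correlation; 0.344 without control replicate 2 and 0.0759 without L.J. replicate 3). The cell cycle list had -0.21 (adjusted p = 0.00428, adjusted p = 0.533 with an estimated correlation; 0.988 without L.J. replicate 3). The lymphocyte list had 0.13 (adjusted p = 0.0122, adjusted p = 0.533 with an estimated correlation; 0.133, 0.0644 and 0.0806 without L.J. replicate 2, L.J. replicate 1 and control replicate 1). The immediate early list had 0.08 (adjusted p = 0.00222, adjusted p = 0.551 with an estimated correlation), and -0.28 without L.J. replicate 3 (adjusted p = 0.988). Without L.J. replicate 1 the medians of the meiotic, piRNA and immediate early lists were -0.32, -0.49 and 0.32. Without L.J. replicate 3 those of the extracellular matrix, antioxidant, meiotic, piRNA and cell cycle lists were -0.75, -0.62, -0.06, -0.10 and -0.11. Without L.J. replicate 2 those of the extracellular matrix, antioxidant and lymphocyte lists were -0.16, -0.07 and 0.08, and without control replicate 3 that of the lymphocyte list was 0.21. The epididymis list, which camera did not call, had a median of 0.26 and a mean of -0.26. Camera called it without control replicate 2 (0.34, adjusted p = 0.0466) or 3 (0.21, adjusted p = 0.0188), and its median was 0.04 and 0.43 without control replicate 1 and L.J. replicate 3. Of the lists camera did not call, Il18 (-0.62), a cytokine of the inflammation list, passed when adjusted over the list alone.

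The test of the interaction asks whether the effect of L.J. differs with busulfan. No gene passed limma's threshold (lowest adjusted p = 1), and 182 genes, 1.24%, lay at an unadjusted p under 0.05. The genes with the smallest p were Serpina1a (1.82), Slc25a29 (1.17), Lrrc17 (1.44), LOC100862433 (-1.56), Zfp868 (-1.11) and Dynlt1a (-1.07), each with an adjusted p of 1. In simulated data, with the same spread per gene in all groups and no low gene changed, 21% of genes with a difference of 1 log2 and 72% of those with 2 were recovered. Without busulfan replicate 3, Vgll2 passed (4.88, adjusted p = 0.0156). Camera called 7 of the 28 lists, and none with an estimated correlation or by fry.

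The comparison of busulfan plus L.J. with control asks what is left of the difference from control when both were given. The lists of elongating and round spermatids were higher than in control in the libraries labelled busulfan plus L.J., and those of Sertoli and Leydig cells lower as deposited, at -0.04 and -0.07 when scaled to Sertoli markers. Tnp2 was 10780 ± 1651 FPKM (SD, n = 3) against 966 ± 840, a log2 change of 3.82 ± 0.65 (SE), and Agt, the precursor of angiotensin, was 52.4 ± 9.97 against 287 ± 67.6, a log2 change of -2.42 ± 0.39. The largest increases were those of Zc2hc1b (4.03), Tnp2, Arl9 (3.77), Prm2 (3.73), Tppp2 (3.71), Spata3 (3.66), Tnp1 (3.61) and Smcp (3.55). Igfbp3 (-2.66), Agt, Scd1 (-2.32) and Cpe (-2.31) were among the 8 largest decreases. The other 4 rested in part on control replicate 3. Those were Crisp1 (-4.39), Akr1b7 (-3.46), Spink8 (-3.03) and Cuzd1 (-2.44), and without that library they had -2.24, -1.56, -1.35 and -1.09 (limma's adjusted p = 0.127 for Crisp1, 0.0662 for Spink8 and 0.0735 for Cuzd1, with Akr1b7 still past the threshold). Without busulfan plus L.J. replicate 1, 2 or 3 it was 0.0732, 0.0609 and 0.0782 for Crisp1, 0.0520, 0.0630 and 0.0588 for Akr1b7, 0.0710, 0.0696 and 0.0621 for Spink8 and 0.0692, 0.0637 and 0.0733 for Cuzd1.

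In all, 9759 genes passed limma's threshold in busulfan plus L.J. against control, 1903 higher and 7856 lower, and a fit of these 2 groups alone called 11189. The groups did not overlap for 11842 genes, 80.7%, where chance gives 10%. Of the calls, 19.5% were higher as deposited, 44% after quantile normalization, 65.6% after median scaling and 99.9% after scaling to Sertoli markers, where the median change of all genes was -0.55, -0.17, 0.05 and 0.98. Camera called 7 of 28 lists, all with an adjusted p of 0.875 with an estimated correlation, and fry called 21. The elongating spermatid list (2.64; 24 of 26 genes higher), round spermatid list (1.13; 14 of 22) and lymphocyte list (0.63; 4 of 6) had medians above 0 under each scaling. The limit that the filter sets for the lymphocyte list, given above, holds here too. The sperm glycolysis list (0.03; 7 of 17 higher, 6 when adjusted over the list alone) turned to -0.12 after quantile normalization, and lay between -0.01 and 0.10 with 1 library left out. The Sertoli (-1.57; 23 of 23 lower) and Leydig lists (-1.60; 17 of 18 lower, 18 when adjusted over the list alone) stayed below 0, but only at -0.04 and -0.07 scaled to Sertoli markers. The first of these is set by that scaling, and the second leaves little of the decrease. The list of cholesterol synthesis (-1.22; 16 of 19 lower, 17 when adjusted over the list alone) turned to 0.31 when scaled to Sertoli markers, and its adjusted p of 0.0226 became 0.0846 without L.J. replicate 3.

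The comparison of busulfan plus L.J. with L.J. was added after the data were seen, because it shares no library with busulfan against control. Late spermatid genes were again higher in the libraries labelled with busulfan, and Sertoli genes lower. Prm2 was 10090 ± 1353 FPKM (SD, n = 3) against 2483 ± 2256, a log2 change of 2.38 ± 0.66 (SE), and Serpina5, a protease inhibitor, was 29.3 ± 1.69 against 174 ± 162, a log2 change of -2.12 ± 0.50. Across the 14675 genes, which are not independent replicates, the changes in both comparisons had a Pearson correlation of 0.93. Of the calls, 7087 genes passed in both in the same direction, 0 in opposite directions, and 3210 are expected in the same direction if the calls were independent. Both sets of calls use the same spread per gene from 1 fit, so they depend on each other even without a shared effect. The 3210 is therefore no strict reference. In all 7556 genes passed limma's threshold, 1719 higher and 5837 lower, with a median change of all genes of -0.40 as deposited, 0.07 after median scaling and 1.10 after scaling to Sertoli markers.

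These calls, though not the median change of all genes, depended on the fit and on single libraries. A fit of the 2 groups busulfan plus L.J. and L.J. alone called 0 genes, with 6787 at an unadjusted p under 0.05 and a median change of all genes still at -0.40. Without busulfan plus L.J. replicate 3 limma called 0 genes while that median was -0.39, and without replicates 1 and 2 of that group 3871 and 3573. The groups did not overlap for 9157 genes, 62.4%, where chance gives 10%. Higher calls were 22.8% as deposited, 57.1% after quantile normalization, 77.8% after median scaling and 100% after scaling to Sertoli markers. Camera called 5 of 28 lists, each with an adjusted p of 0.934 with an estimated correlation, and fry called 1. Those were elongating spermatids (1.93; 24 of 26 higher), round spermatids (1.08; 14 of 22 higher), Sertoli cells (-1.51; 21 of 23 lower; 0.00 scaled to Sertoli markers), sperm glycolysis (0.27; 7 of 17 higher, 6 when adjusted over the list alone) and apoptosis (-0.83; 14 of 22 lower; 0.68 scaled to Sertoli markers). Without L.J. replicate 3 the medians of round spermatids, Sertoli cells, apoptosis and sperm glycolysis were 0.66, -0.85, -0.48 and -0.02, and without L.J. replicates 1 and 2 that of sperm glycolysis was 0.52 and 0.44. The glycolysis call was lost without that library (adjusted p = 0.0926), and the apoptosis call without it (0.0740) or busulfan plus L.J. replicate 2 (0.0558).

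The named genes of busulfan plus L.J. against L.J. lost their calls by limma without busulfan plus L.J. replicate 3, with adjusted p from 0.0544 to 0.0700, while none of their changes moved by over 1.5 times. The other increases among the 8 largest were those of Mup1 (2.78), Tcte3 (2.44), Zc2hc1b (2.39), Tppp2 (2.39), Smcp (2.33), Prm3 (2.32) and Arl9 (2.31). The other decreases were those of Apod (-2.45), Fabp5 (-2.14), Cpe (-2.09), Igfbp3 (-2.09), Lipg (-2.05), Ddr1 (-2.04) and Cnn3 (-1.98). Limma's adjusted p of Mup1 passed 0.05 without any 1 of the 6 libraries, from 0.0538 without L.J. replicate 3 to 0.108 without busulfan plus L.J. replicate 1, where its change was 1.5. It was 0.0723 and 0.0559 without L.J. replicates 1 and 2, and 0.0559 and 0.0544 without busulfan plus L.J. replicates 2 and 3. Without busulfan plus L.J. replicate 1 it was 0.0597 for Tcte3, 0.0616 for Apod and 0.0579 for Igfbp3. Without busulfan plus L.J. replicate 2 it was 0.0594, 0.0614 and 0.0672 for these, 0.0506 for Smcp, 0.0513 for Ddr1 and 0.0514 for Fabp5. Without L.J. replicate 1 it was 0.0528 for Smcp and 0.0519 for Prm2. Without L.J. replicate 3 the changes were -1.41 for Apod (adjusted p = 0.0584), -1.28 for Fabp5 and Cpe, -1.39 for Serpina5, -1.11 for Igfbp3, -1.12 for Cnn3 and -1.18 for Ddr1, and without L.J. replicate 2 that of Tcte3 was 1.29.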

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

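The tests of 3 patterns below were all chosen after the result was seen, whereas the splits of the libraries were planned. In 7 gene lists the effect of L.J. differed between libraries labelled with and without busulfan, by a camera test of the interaction. The median interaction was -0.59 for elongating spermatids (adjusted p = 1.73e-09), 0.66 for Leydig cells and steroidogenesis (3.07e-09), 0.46 for peritubular myoid cells (0.0370), 0.32 for extracellular matrix (1.27e-05), 1.08 for erythroid cells (0.000189), 1.21 for adipocytes (1.11e-07) and 0.57 for cholesterol synthesis (4.81e-12). With an estimated correlation the adjusted p by camera were 0.787, 0.392, 0.935, 0.866, 0.392, 0.392 and 0.392, and by fry no list passed. The sign of each median was the same under the 3 scalings. Without L.J. replicate 2 the medians of elongating spermatids, Leydig cells and steroidogenesis, peritubular myoid cells, extracellular matrix and cholesterol synthesis were 0.03 (adjusted p by camera 0.800), 0.33, 0.19 (0.164), 0.16 and 0.30. Without control replicate 3 those of elongating spermatids, peritubular myoid cells, extracellular matrix, erythroid cells and adipocytes were -0.18, 0.06 (adjusted p by camera 0.667), 0.20, 0.66 and 0.73. Without control replicate 2 those of elongating spermatids, peritubular myoid cells and extracellular matrix were -1.18, 0.79 and 0.57. Without L.J. replicate 3 they were -1.08, 0.88 and 0.79, and the calls of erythroid cells (adjusted p by camera 0.125) and adipocytes (0.114) were lost while their medians stayed at 0.92 and 1.01. The call of peritubular myoid cells was also lost without L.J. replicate 1 (0.330), busulfan replicate 1 (0.214) and busulfan plus L.J. replicate 3 (0.101), and that of erythroid cells without busulfan plus L.J. replicate 3 (0.0553, median 0.58). The median of erythroid cells was 1.64 without L.J. replicate 1. Of 100 splits, 89 gave at least 7 such lists, with up to 21, so chance is not excluded for this count.

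Spermatid transcripts were higher and, as deposited, somatic transcripts lower in the libraries labelled busulfan than in those labelled control. The values go against a lower share of spermatids in the libraries labelled busulfan, but they restate the pattern and are no separate test. Of 2 spermatid lists, 2 were higher in each of those libraries than in each control library, as deposited and relative to Sertoli markers. Those markers were lower themselves in busulfan as deposited. Relative to them elongating spermatids had 5.26 on average in busulfan (5.10 to 5.40) and 1.26 in control (0.22 to 2.74). A few abundant spermatid genes that lower all other FPKM are argued against as the whole cause, because the Sertoli median was -1.43 (upper quartile -1.27) after scaling without the 500 most abundant genes, and -1.53 before. A loss of spermatogonia and spermatocytes is open, as the medians of their lists were -0.69 and -0.54 as deposited and 0.78 and 0.93 scaled to Sertoli markers, which fell themselves. Exchanged labels of the busulfan and non-busulfan libraries and an effect of busulfan, at a dose and time that the labels do not give, cannot be told apart, because for elongating spermatids relative to Sertoli markers the lowest busulfan plus L.J. library also lay 1.26 above the highest L.J. library, which either would give.

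Transcripts of epididymis and fat were high in control replicate 3, where 9 of 12 adipocyte genes had their highest value of all 12 libraries, a count that restates the pattern. Fat carried over at dissection is open. Of 20 other fat genes, 9 peaked there, above the 95th percentile of 7 in 10000 random draws of as many genes. However, 12 of 18 Leydig genes peaked there too, a comparison added once that count was known. Of the 20, 12 were at 1 FPKM or more in each library. Acsl1 and Gpd1, the most abundant of the 20 in control replicate 3 at 37.6 and 33.0 FPKM, had their highest values in other libraries. Those that peaked there were Mrap (15.9 FPKM), Cebpa (5.27), G0s2 (4.3), Slc2a4 (2.88), Pck1 (2.65), Pparg (2.33), Trarg1 (0.69), Lgals12 (0.45) and Adrb3 (0.33). Epididymis carried over is open, as 4 of 16 epididymis genes had their highest value there, with a median of 3 and a 95th percentile of 6 in the draws. Those 4, Crisp1, Adam7, Rnase9 and Spinkl, were 503, 14.4, 11.7 and 1.64 FPKM there. In the other 2 control libraries they were at most 15.1, 0.41, 0.25 and 0.1 FPKM. Against that, Lcn5, Lcn8 and Lcn9 of the same list were 0 in control replicate 3. The high values were not confined to control replicate 3. In L.J. replicate 3 Crisp1, Adam7 and Rnase9 were 33.6, 2.74 and 1.4 FPKM, above all libraries but control replicate 3. Spinkl was 0.33 FPKM in L.J. replicate 3, below its 0.37 and 0.4 in busulfan replicates 2 and 3. A larger share of all somatic cells is open, since the excess over the other 2 control libraries was 1.25 for the adipocyte list (quartiles 0.61 and 1.81) and 0.97 for the epididymis list, but 1.18 for the myoid list (0.63 and 1.58) and 0.36 to 0.65 for the Leydig, Sertoli, matrix, macrophage and endothelial lists, so that the differences of 0.07 between adipocyte and myoid lists and of 0.53 between epididymis and Leydig lists decide neither way. No biological explanation was tested, since the design gives none for a single library.

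Leydig genes were lower in the libraries labelled L.J. than in those labelled control. The pattern may rest largely on 1 library, as the median of the list was -0.27 without L.J. replicate 2 and between -0.92 and -0.63 without any other of the 6, though the adjusted p by camera stayed at 0.000566 without that library. That value holds at the preset correlation. With an estimated correlation or by fry no list passed in this comparison, and no gene passed over all genes. With the share of spermatids against Sertoli cells as a covariate the median went from -0.76 to -0.54, with 15 of 18 genes below 0 and an unadjusted p by camera of 0.000242, which speaks against that share as the whole cause but, with quartiles from -0.88 to -0.14, does not exclude it. Fewer Leydig cells are open as well, because the other genes of the list minus Insl3 were -5.70 in L.J. and -5.93 in control but -5.69 in busulfan plus L.J. and -5.41 in busulfan, and the mean difference of -0.02 (two-sided exact permutation p = 0.925 over 400 arrangements) averages opposite signs and decides nothing. An effect of L.J. on androgen synthesis stays among the open explanations, untested.

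In the comparisons of 3 libraries with 3 the 10 splits cannot give a share under 0.1. The real counts of genes and the highest among the other splits were 9350 and 0 for busulfan against control, 9759 and 1 for busulfan plus L.J. against control, and 7556 and 1 for busulfan plus L.J. against L.J., each reached by 1 of 10 splits. They were 0 and 0 for busulfan plus L.J. against busulfan and 0 and 6569 for L.J. against control, by limma, each reached by 10 of 10. For lists by camera they were 10 and 14 (5 of 10 splits), 7 and 18 (8 of 10), 5 and 18 (10 of 10), 2 and 7 (6 of 10) and 11 and 18 (9 of 10) in the same order. The split with 6569 genes set L.J. replicates 1 and 2 and control replicate 2 against the other 3 libraries, which points to a structure of the samples that crosses the labels. For the interaction and the restored genes, 100 of 100 splits gave at least the real counts of 0 by limma, with up to 3674 and 1. Any split reaches a count of 0, so for the counts of 0 the splits decide nothing about chance.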

How the results depend on the processing

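The comparison of busulfan plus L.J. with L.J., the array weights estimated gene by gene, the covariate and the fit without L.J. replicates 2 and 3 were chosen after the data were seen. In order, genes changed by limma in busulfan against control, busulfan plus L.J. against control and busulfan plus L.J. against L.J. were 5209, 6013 and 3544 after quantile normalization, 4519, 5238 and 3356 after median scaling, 2932, 3892 and 5184 after scaling to Sertoli markers, and 3715, 4192 and 2574 at a log2 fold of at least 1. Of the 2932 genes, 1774 were also called as deposited, counted whatever their direction. After scaling to Sertoli markers 2931 of the 2932 were higher, whereas 7536 of 9350 were lower as deposited, so the 1774 do not measure agreement. With 1 library left out the counts of genes in the 3 comparisons ranged from 5842 to 10909, from 6973 to 11258 and from 0 to 9385. The lowest were without control replicate 3 for the first and busulfan plus L.J. replicate 3 for the last. A fit of only the 2 groups called 0 genes in busulfan plus L.J. against L.J. and 1 in busulfan plus L.J. against busulfan. With no filter 1 gene was called in busulfan plus L.J. against busulfan (Defb13), 1 in the interaction (Defb13) and 1 gene was restored. With 1 library left out these 3 counts ranged from 0 to 1, reaching 1 without busulfan replicate 3, and 0 genes changed in L.J. against control, where 715 lay at an unadjusted p under 0.05 with all libraries. The covariate gave 0 there too.

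Array weights did not converge, with weights from 9.13e-13 for L.J. replicate 1 to 2140 for busulfan replicate 3, so counts with them are not reliable. They were 14310 for busulfan against control, 2439 for busulfan plus L.J. against busulfan, 5 for L.J. against control (Bpifb5, Tcte3, Cyp17a1, Ugt1a6b and Cyp11a1), 2 for the interaction (Tcte3 and Ugt1a6b), 1 for busulfan plus L.J. against L.J. (Tcte3) and 1294 restored genes. Estimated gene by gene the weights ran from 0.064 for L.J. replicate 3 to 7.82 for busulfan replicate 3. The counts were then 64 for busulfan plus L.J. against busulfan, 5162 for L.J. against control, 2523 for the interaction and 36 restored genes, and Clu turned to -0.75 in L.J. against control.

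Lists past the threshold numbered 10 in busulfan against control, 2 in busulfan plus L.J. against busulfan, 11 in L.J. against control, 7 in busulfan plus L.J. against control, 7 in the interaction and 5 in busulfan plus L.J. against L.J. by camera. They were 0 in all 6 with an estimated correlation, and 18, 0, 0, 21, 0 and 1 by fry. Scaling to Sertoli markers gave 16, 5, 9, 14, 9 and 11. With the replicate block they were 11, 5, 11, 12, 9 and 6, and 9591 genes changed in busulfan against control. The replicate numbers were not taken to pair the samples, since 5 of 18 pairs with the same number had a correlation of their deviations above 0.1. As a hint of pairing in part, 9 of 12 libraries correlated best with one of their own number, and the correlation was 0.76 between control and L.J. replicates 2 and 0.62 between their replicates 3.

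A named gene is called reversed where the sign of its change turned, whether or not the new value passed. Named genes reversed in busulfan against control after median scaling were Sycp3 (0.05) and Sycp1 (0.09). After scaling to Sertoli markers they were Sycp3 (0.95), Sycp1 (1.00), Dmc1 (0.63), Zbtb16 (0.59), Kit (0.11), Sox9 (0.28), Wt1 (0.00), Cdkn1a (0.67), Bax (0.06), Mki67 (0.87), Dbp (0.00), Jun (0.52), H2-K1 (0.05), Tapbp (0.46) and Psmb8 (0.76). Values near 0, such as those of Wt1, Dbp, Bax and H2-K1, show a lost change rather than an opposite one. In L.J. against control Clu was reversed, at -0.75, with array weights estimated gene by gene. No other gene named in the text that passed before or after a change of setting reversed. With 1 library left out 129 calls were lost, 7 gained and 1688 results kept their side of the threshold. The cause of these changes, scalings apart, was not tested. The depth is unknown, so what it limits cannot be given.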
